A study of Drosophila melanogaster with 12 samples.

How the data were processed

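The series holds 12 single-colour Affymetrix 3' arrays of Drosophila melanogaster, 3 for each of whole fly and midgut on an unmodified or glucose-enriched holidic diet. Per the labels' protocols, total RNA was extracted with Trizol from 5 whole flies or 10 dissected midguts and made into biotin-labelled cRNA. The deposited table holds 1 log2 probe set signal per array. Per the submitters' processing notes it was made with Affymetrix Expression Console; its version, the summarisation algorithm and whether the tissues were normalized together are not given in the sources used here. The log2 scale was read from the values, which lie between 1.44 and 14.1 over the arrays. Signals of dim probe sets sit near background, where differences are compressed.

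The table has 18952 probe sets, of which 183 Affymetrix controls were left out and 18769 tested. In the platform annotation supplied, 13647 probe sets carry 1 gene symbol, 402 carry several and were not named, and 4720 carry none listed, giving 11982 distinct named genes. Symbols were checked through gene identifiers against a RefSeq gene table, which changed 0 symbols, while 103 named probe sets had an identifier that the table lacks. The table served for names only, since the deposited values name no genome build, and no coordinates are given. Within a group the largest share of probe sets with identical values in a pair of arrays was 0.021%, so no sample was counted as a duplicate.

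Each diet comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values of the 6 arrays of that tissue, as glucose minus unmodified, with no covariate. The difference between the diet effects and the contrast of midgut against whole fly on the unmodified diet were fitted over all 12 arrays. Two-sided p-values were adjusted by Benjamini-Hochberg over all tested probe sets, and an adjusted p under 0.05 was called. Overlaps were tested by Fisher's exact test, one-sided. With 3 samples against 3, an exact permutation test of a single gene cannot go below 0.1, so per-gene results rest on the variance limma shares across probe sets.

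Before the data were examined, 41 gene lists were fixed, covering digestion, metabolism, immunity, stress, junctions, cell division and markers of midgut and other tissues, and all had at least 3 measured members. Each was tested with camera at its preset inter-gene correlation of 0.01, on 1 probe set per gene, the one with the highest mean over the 12 arrays, adjusted over lists within a comparison. Lists were not always fully measured. Measured were 5 of 13 photoreceptor genes, 23 of 70 cytosolic ribosomal proteins, 6 of 14 antimicrobial peptides and 3 of 7 lysozymes. Camera with an estimated correlation, fry and the average of a gene's probe sets were alternatives. Named genes followed a rule fixed at the same time. For each comparison these were the 10 genes with the largest positive and the 10 with the largest negative difference among probe sets with 1 gene, an adjusted p under 0.05 and no overlap between the 3 arrays of each group. For the difference of diet effects it was 5 and 5 without the condition on arrays. Up to 4 members of a described list with the smallest p were added, plus any member without which the call of the list would be unclear.

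Replicate numbers in the titles were tested for pairing. Deviations from the group means correlated between same-numbered midgut samples at 0.39, 0.31 and 0.36, all over 0.1, so in midgut the numbers were taken to pair the samples and blocked values are given beside results they change. This pairing comes from the data, as the labels do not state what a number shares.

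The fits were tested on simulated data, 10 sets per tissue of 18769 probe sets with 200 changed, drawn from the fitted means and from variances drawn from their posterior. A first version used the fitted variances themselves, which gave less spread between probe sets and higher recovery, and was replaced. For midgut, 10.3%, 80.0% and 96.9% of probe sets changed by 0.5, 1 and 2 on the log2 scale were recovered, and 4.7% of calls were false. For whole fly these were 7.1%, 75.7% and 97.6%, with 4.3% false. A list shifted by 0.5 was called in 10 of 10 sets in each tissue, and of 200 unshifted lists 10 were called in midgut and 7 in whole fly at an unadjusted p under 0.05. The simulation has no correlation between genes, which real lists have. Its recovery holds for 200 changed probe sets, since the adjustment depends on how many change, and need not hold for data with fewer. In the midgut data 46 probe sets had an unadjusted limma p under 0.05 and a 2-fold difference, and 1 was called.

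Alternatives set before the data were examined were the removal of the 40% of probe sets with the lowest mean, eBayes with trend and robust prior, median centring, quantile normalization, array weights, 2-fold thresholds, the replicate block, shared or separate fits and leaving out each array. A covariate for the difference between the 3' and 5' probe sets of control transcripts was added after the data were seen.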

Results

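Gene expression was measured with Affymetrix 3' expression arrays in adult female Drosophila melanogaster of the w1118 strain, a white-eyed laboratory stock. From eclosion the flies were kept for 10 days at 25 °C on a holidic diet, which is a fully defined synthetic food, either unmodified or enriched with glucose (100 g/L; whether this is the amount added or the final one is not stated). Each sample was RNA from 5 whole flies or from 10 dissected midguts, with 3 samples for each combination of tissue and diet and 12 arrays in all. Array medians were 4.04 to 4.15 on the log2 scale in whole flies and 3.43 to 3.47 in midguts. Correlations between arrays of a group, across 18769 probe sets, lay between 0.9887 and 0.9939, and between tissues between 0.836 and 0.903. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, and the number of arrays limits the precision.

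The first comparison asked which genes of the midgut differed after 10 days on the glucose-enriched diet. One named gene passed the test. CG1648 rose by 1.49 (SE 0.11) on the log2 scale, from 8.34 ± 0.10 to 9.83 ± 0.12 (SD, n = 3), with a limma adjusted p of 0.0157. It was the only one of 18769 probe sets with an adjusted p under 0.05, against 1164 at an unadjusted p under 0.05, of which 652 were higher and 512 lower on glucose. No probe set was called when any 1 of the 6 arrays was left out. The arrays of the 2 diets did not overlap for 2197 probe sets, or 11.7%, where chance gives 10%.

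Same-numbered midgut samples deviated together, and with the replicate number as a block 24 probe sets were called, 10 higher and 14 lower, among them CG1648. The blocked calls were read after the data were seen, by the same rule for naming genes. Amyrel, an amylase-related gene, fell by 1.56 (SE 0.12, blocked adjusted p 0.0137), from 6.04 ± 0.41 to 4.48 ± 0.15. The maltase gene Mal-A4 fell by 1.22 (SE 0.14), the lipase-family gene CG6283 by 1.26 (SE 0.14), the sterol-binding gene Npc2e by 0.87 (SE 0.09) and the serine protease gene Jon66Cii by 1.02 (SE 0.12). The metallothioneins MtnB and MtnD, small metal-binding proteins, fell by 1.41 (SE 0.10, blocked adjusted p 0.00772) and 1.18 (SE 0.13). CG15533, CG8997 and CG7968 also fell, by 1.87, 1.57 and 1.13. Outside the rule, the maltase gene Mal-B1 fell by 1.30 (SE 0.16, blocked adjusted p 0.0484) and CG42335 by 1.26 (SE 0.14), and the other 2 lower probe sets had no gene listed. Of the 10 that rose, the largest, at 1.80 (SE 0.19), had no gene listed, and the other 9 carried CG numbers. Besides CG1648 these were CG13215, CG13616, CG9825, CG30334, CG32751, CG30281, CG13877 and CG33494, at 0.90 to 1.61. Without the block the adjusted p of MtnB was 0.0721 and that of Amyrel 0.0941.

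**Figure D1:**
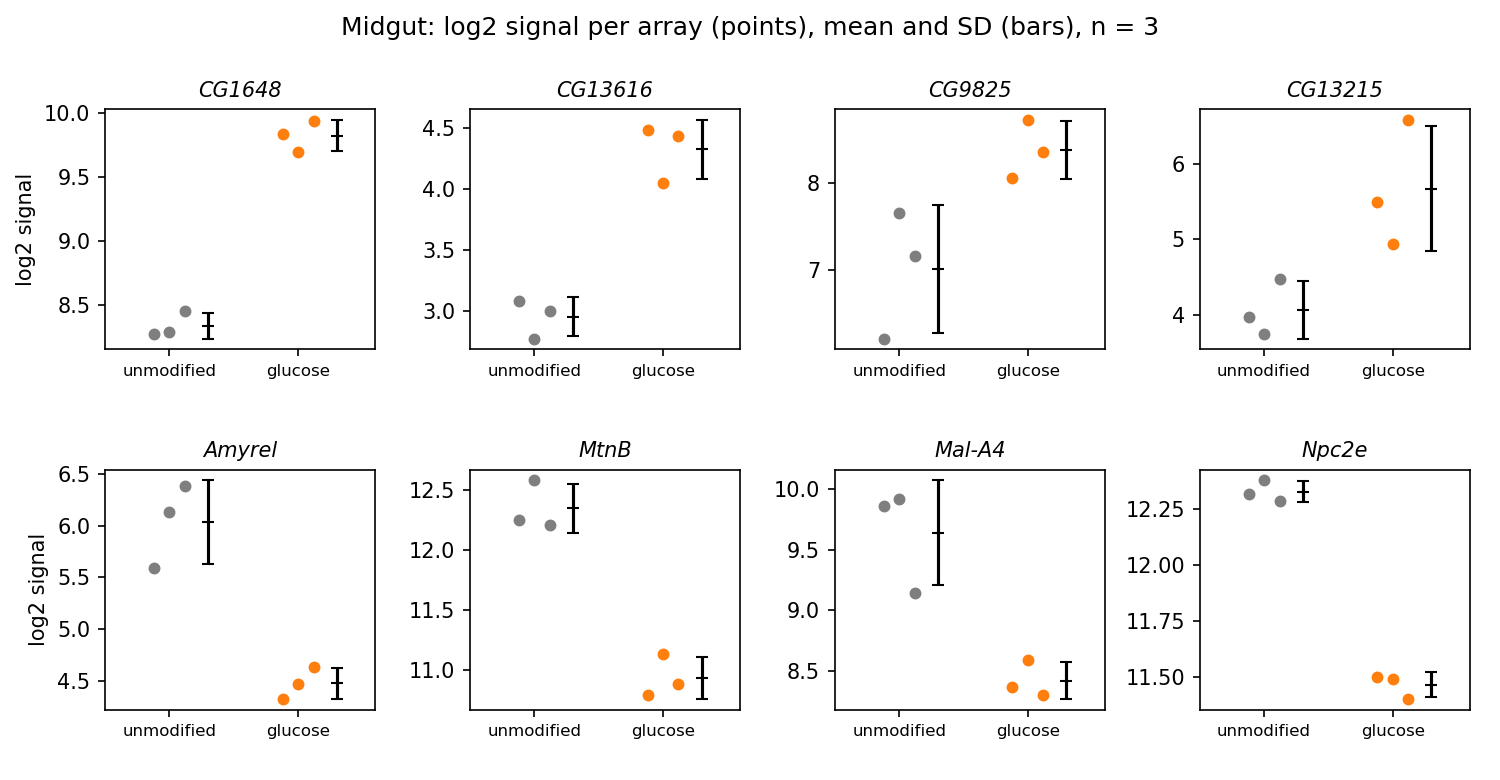
Log2 signal of 8 genes in the 3 midgut samples on each diet, with points for arrays and bars for mean and SD, on separate vertical scales. CG1648 lies near 8.34 on the unmodified and 9.83 on the glucose diet, and MtnB near 12.3 and 10.9; of the 8 genes CG1648 passed the test without the replicate block and all 8 passed with it.

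Of 41 gene lists fixed before the data were examined, 7 were called in midgut by camera, 1 higher and 6 lower. The amylase, maltase and lysosomal mannosidase list, enzymes that split sugar chains, fell with a median of -0.58 over 18 genes (adjusted p 6.63e-09), which was -0.32 without unmodified replicate 1. None of its members passed over all probe sets, and 4 passed lower adjusted over the list alone: Amyrel, Mal-A4, Mal-A3 at -0.86 (SE 0.25) and Mal-A6 at -0.65 (SE 0.19). The list of glutathione transferases and cytochrome P450s, which conjugate or oxidise foreign compounds, fell with a median of -0.36 over 24 genes (adjusted p 6.63e-09), with no member passing in either way of adjusting. Its smallest p-values belonged to GstE7 at -0.54 (SE 0.13), GstD10 at -1.08 (SE 0.29), Cyp6g1 at -0.53 (SE 0.15) and GstD4 at -0.60 (SE 0.18). With a correlation estimated from the residuals neither list was called, with adjusted p = 0.478 and adjusted p = 0.199. In all 3 same-numbered midgut pairs the 3' to 5' difference of the gapdh control was higher on glucose, by 0.04 to 0.46, as were the dap spike, by 0.46 to 0.47, and the bioB spike, by 0.17 to 0.35. The act5C and eif4a differences were higher in 2 of 3 pairs.

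The digestive lipase and sterol uptake list fell with a median of -0.27 over 11 genes (adjusted p 1.19e-05; adjusted p = 0.338 with an estimated correlation). Without 1 array its median ranged from -0.14 to -0.68. No member passed over all probe sets and 4 passed lower adjusted over the list alone, Npc2e, CG8093 at -2.32 (SE 0.28), CG6283 and Lip3 at -0.83 (SE 0.17). The list of metallothioneins, ferritin and metal transport fell with a median of -0.25 over 11 genes (adjusted p 4.11e-05; adjusted p = 0.199 with an estimated correlation). There 3 members passed lower adjusted over the list alone and none over all probe sets: MtnB, MtnD and the transferrin gene Tsf1 at -1.72 (SE 0.47). Secreted serine proteases of digestion fell with a median of -0.13 over 23 genes (adjusted p 0.00127; adjusted p = 0.510 with an estimated correlation), with 2 lower members adjusted over the list alone, Jon66Cii and Jon66Ci, and none over all probe sets. This call was lost without glucose replicate 3, and the median ranged from -0.17 to -0.07 without 1 array.

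Cytosolic ribosomal protein genes rose with a median of 0.13 over 23 genes (adjusted p 4.11e-05; adjusted p = 0.859 with an estimated correlation). No member passed in either way of adjusting, and RpL17 at 0.31 (SE 0.11) had the smallest p. Midgut glucose replicate 1 also carried the oogenesis transcripts orb at 6.32, Marf1 at 5.62 and Vm26Aa at 8.23, against at most 2.57, 2.44 and 5.42 in the other glucose samples. Unmodified replicate 1 had Marf1 at 4.35, against 2.21 and 2.42 in the other unmodified samples, with orb at 2.81 and Vm26Aa at 4.40. Without glucose replicate 1 the list median was 0.10. The yolk, vitelline membrane and chorion list, genes of egg formation, fell with a median of -0.28 over 20 genes (adjusted p 4.94e-04; adjusted p = 0.657 with an estimated correlation), again with no member passing. Its smallest p-values belonged to the yolk proteins Yp2 at -0.54 (SE 0.13) and Yp3 at -0.42 (SE 0.12), and the call was lost without glucose replicate 3 and in the fit over 12 arrays. Without 1 array the median ranged from -0.36 to -0.16. For 7 of the 20 genes the midgut means lay below the array median on both diets. The list stood at a median of -4.58 in midgut against whole fly on the unmodified diet. With the replicate block 9 lists were called, the other 2 being enteroendocrine peptides and Malpighian tubule markers (both at a blocked adjusted p of 0.0393, against 0.0540 and 0.0993 without it). Their medians were -0.18 and -0.32, in the direction of the digestive and detoxification lists. Lists of the septate junction, which seals the gaps between gut cells, of midgut progenitors, of cell division and of antimicrobial peptides were not called in midgut, with medians of 0.10, -0.13, 0.03 and 0.06 and adjusted p-values of 0.168, 0.806, 0.923 and 0.937.

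The second comparison asked the same of whole flies. There 584 probe sets, 3.11% of those tested, had a limma adjusted p under 0.05, of which 247 were higher and 337 lower on glucose, for 209 and 289 named genes. Of these probe sets 119 differed at least 2-fold, 87 higher and 32 lower. The genes with the largest increases were LysX, a lysozyme gene, which rose by 4.03 (SE 0.73), from 5.97 ± 1.70 to 10.0 ± 0.42 (SD, n = 3, limma adjusted p 0.0395), and CG13947, which rose by 2.59 (SE 0.50). The non-coding RNA lncRNA:CR32368 and the genes CG7567, CG17224, CG8353, CG10154, CG1648, CG9825 and CG34232 rose by 1.51 to 2.51. The chorion gene Cp15 fell by 4.24 (SE 0.70), from 12.8 ± 0.91 to 8.52 ± 1.42 (adjusted p 0.0371). Among regulators of early development, hb, encoding the gap transcription factor Hunchback, fell by 1.37 (SE 0.23), and zld, encoding the transcription factor Zelda that opens the early zygotic genome, fell by 1.28 (SE 0.21). The junction-associated gene cno fell by 1.37 (SE 0.14, adjusted p 0.0310), Zdhhc8, of the palmitoyltransferase family, by 1.23 (SE 0.25), and CG8093 by 2.04 (SE 0.34). CG9993, CG15533, CG6283 and CG43759 fell by 1.24 to 1.36.

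**Figure D2:**
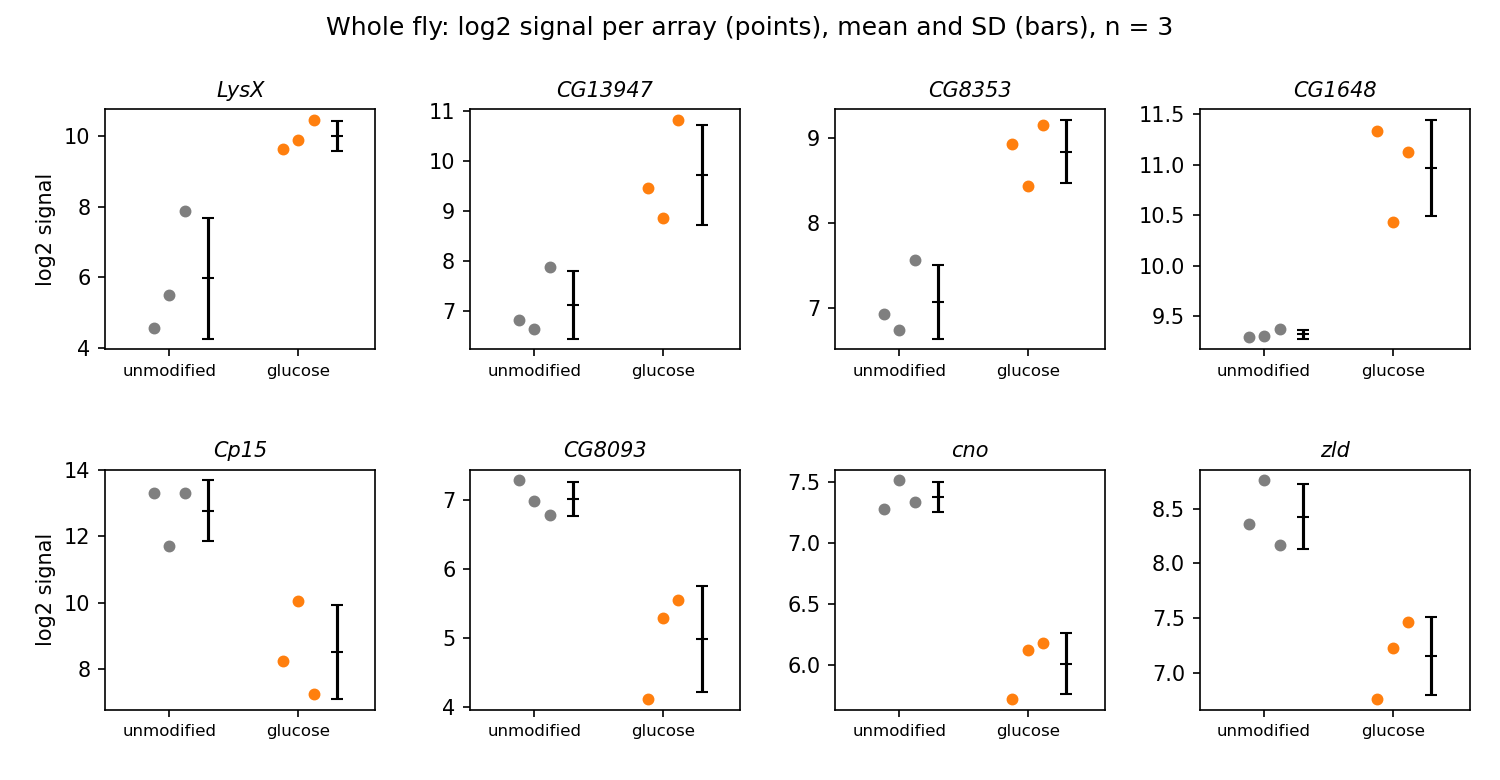
Log2 signal of 8 genes in the 3 whole fly samples on each diet, with points for arrays and bars for mean and SD, on separate vertical scales. All 8 passed the test, with LysX at means of 5.97 and 10.0 and Cp15 at 12.8 and 8.52 on the unmodified and glucose diets.

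The count of calls in whole flies rested on the set of arrays. The adjusted p-values of the calls lay between 0.0310 and 0.0499. Without unmodified replicate 1, 2 or 3 the count was 0, 1 and 1, without glucose replicate 1 or 3 it was 0 and 2, and without glucose replicate 2 it was 1563.

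Of the 41 lists, 19 were called in whole flies, 16 higher and 3 lower. None was called with an estimated correlation, where the adjusted p-values of these 19 lay between 0.322 and 0.471. Cell division genes fell with a median of -0.76 over 14 genes (adjusted p 2.22e-07; adjusted p = 0.322 with an estimated correlation). Over all probe sets 4 members passed, all lower, and adjusted over the list alone all 14 did: fzy, an activator of the anaphase-promoting complex, at -0.79 (SE 0.15), the cyclin gene CycE at -0.96 (SE 0.19), and the replication genes dup at -0.84 (SE 0.17) and Mcm5 at -0.69 (SE 0.14). Germline genes fell with a median of -0.37 over 13 genes (adjusted p 0.00520; adjusted p = 0.322 with an estimated correlation), with 2 lower members over all probe sets, orb and swa, both at -0.74, and 6 lower and 1 higher adjusted over the list alone. The higher one was grk, which encodes the oocyte signal Gurken, at 0.36 (SE 0.12). The yolk, vitelline membrane and chorion list was not called, at a median of -1.39 over 20 genes (adjusted p 0.172). Cp18 stood at -3.70 (SE 1.70) and Cp36 at 2.14 (SE 1.55), and Cp15 alone passed. Endoplasmic reticulum stress genes fell with a median of -0.21 over 9 genes (adjusted p 0.0344; adjusted p = 0.322 with an estimated correlation), with no member over all probe sets and 3 lower adjusted over the list alone, Ire1 at -0.61 (SE 0.14), Sil1 at -0.41 (SE 0.10) and PEK at -0.76 (SE 0.23). That call was lost under several alternatives, among them the removal of the dimmest 40% of probe sets, and the germline call was lost in the fit over 12 arrays.

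Markers of several adult somatic tissues were higher. All 5 measured photoreceptor genes, of 13 listed, rose over all probe sets and adjusted over the list alone. Their median was 1.19 (list adjusted p 1.72e-05, and adjusted p = 0.322 with an estimated correlation). The light-response channel genes trpl and trp rose by 1.26 (SE 0.19) and 1.25 (SE 0.19), and the scaffold gene inaD by 1.19 (SE 0.21). The arrestin genes Arr1 and Arr2 rose by 1.17 (SE 0.23) and 0.99 (SE 0.20). Muscle genes rose with a median of 0.53 over 13 genes (adjusted p 1.72e-05; adjusted p = 0.342 with an estimated correlation), of which 1 passed over all probe sets, the troponin gene up at 0.53 (SE 0.11), and 8 adjusted over the list alone, among them Act88F at 1.35 (SE 0.29) and Mlc1 at 0.84 (SE 0.19). Hemocyte genes, of the blood cells, rose with a median of 0.67 over 8 genes (adjusted p 6.39e-04; adjusted p = 0.322 with an estimated correlation). Hml at 1.04 (SE 0.21) passed over all probe sets and 5 members adjusted over the list alone, including He at 0.50 (SE 0.12) and PPO2 at 0.60 (SE 0.19). Neuron and Malpighian tubule markers were not called, with medians of -0.10 and -0.03 and adjusted p = 0.935 for both. Oxidative phosphorylation genes rose with a median of 0.22 over 23 genes (adjusted p 1.72e-05; adjusted p = 0.322 with an estimated correlation), 2 of them over all probe sets, ND-18 at 0.58 (SE 0.10) and RFeSP at 0.56 (SE 0.11), and 6 adjusted over the list alone. TCA cycle genes rose with a median of 0.23 over 15 genes (adjusted p 0.00520; adjusted p = 0.448 with an estimated correlation), with SdhC at 0.45 (SE 0.10) the 1 member passing adjusted over the list alone and none over all probe sets. That call was lost without unmodified replicate 2, and the median ranged from 0.12 to 0.30 without 1 array.

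Sugar-sensing regulators and targets rose with a median of 0.61 over 8 genes (adjusted p 0.00128; adjusted p = 0.322 with an estimated correlation). Over all probe sets 4 members passed and adjusted over the list alone 5 did. The transcription factor gene sug, a glucose-responsive repressor, rose by 1.14 (SE 0.15), bigmax, encoding the partner of the sugar sensor Mondo, by 0.58 (SE 0.09), the activin gene Actbeta by 0.71 (SE 0.12) and cbt by 0.63 (SE 0.11). De novo lipogenesis genes rose with a median of 0.21 over 13 genes (adjusted p 0.0141; adjusted p = 0.471 with an estimated correlation). Lpin at 0.53 (SE 0.11) passed over all probe sets and, with FASN2 at 1.08 (SE 0.24), adjusted over the list alone, and the call was lost without unmodified replicate 2 or glucose replicate 1. Without 1 array the median ranged from 0.08 to 0.35. The insulin and adipokinetic signalling list was not called (median 0.10 over 10 genes, adjusted p 0.0717), although 2 members passed, the adipokinetic hormone gene Akh at 0.75 (SE 0.14) and its receptor gene AkhR at 1.58 (SE 0.30). Glycolysis and sugar transporter lists were not called, at medians of -0.01 and -0.06.

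Immune lists and, apart from them, the lysozyme list rose as well. Antimicrobial peptides had a median of 0.80 over 6 genes (adjusted p 0.00168; adjusted p = 0.322 with an estimated correlation), with Def at 0.59 (SE 0.11) passing over all probe sets and Def, DptB at 1.01 (SE 0.21) and Mtk at 3.11 (SE 0.67) adjusted over the list alone. The peptidoglycan recognition and Imd pathway list had a median of 0.34 over 12 genes (adjusted p 0.0257; adjusted p = 0.322 with an estimated correlation). Rel, which encodes the NF-kappaB factor Relish, passed over all probe sets at 0.62 (SE 0.12), and adjusted over the list alone 5 members were higher and 1 lower, the last being PGRP-SC2 at -0.48 (SE 0.17). Without unmodified replicate 2 the list call was lost. Lysozymes rose with a median of 0.54 over 3 genes (adjusted p 0.0176; adjusted p = 0.322 with an estimated correlation), of which LysX passed over all probe sets and LysX and LysS at 0.48 (SE 0.18) adjusted over the list alone. On the unmodified diet all 3 lysozyme genes were called higher in midgut than in whole fly, with a median of 1.45. The rise of this list is therefore not read as an immune response. Without 1 array the median ranged from 0.27 to 0.74 for lysozymes and from 0.22 to 0.52 for the Imd list.

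The other lists called higher in whole flies were circadian clock genes, glutathione transferases and cytochrome P450s, enteroendocrine peptides, midgut progenitor markers, peritrophic matrix and mucins, and antioxidant enzymes, each with an adjusted p = 0.322 with an estimated correlation. The clock genes had a median of 0.43 over 8 genes (adjusted p 0.00702), with none passing over all probe sets and 6 adjusted over the list alone: Pdp1 at 0.47 (SE 0.11), vri at 0.59 (SE 0.14), cry at 0.47 (SE 0.13), Clk at 0.46 (SE 0.13), per at 0.41 (SE 0.13) and tim at 0.29 (SE 0.09). Detoxification genes had a median of 0.19 over 24 genes (adjusted p 0.0171) and 4 passed in both ways of adjusting, Cyp6a2 at 0.76 (SE 0.12), GstD2 at 1.35 (SE 0.25), Cyp6w1 at 0.54 (SE 0.11) and GstE2 at 0.51 (SE 0.10). Enteroendocrine peptides, with 1 member passing over all probe sets and 5 adjusted over the list alone, had a median of 0.24 over 13 genes (adjusted p 0.0174), led by the hormone gene Dh31 at 0.82 (SE 0.15). Midgut progenitor markers had a median of 0.40 over 7 genes (adjusted p 0.0176), where the Notch targets E(spl)m3-HLH at 0.62 (SE 0.11) and E(spl)mbeta-HLH at 0.60 (SE 0.10) passed in both ways. Neither rise was seen in the dissected midguts, where the medians were -0.18 for enteroendocrine peptides and -0.13 for progenitor markers. There the camera adjusted p-values were 0.054 (0.0393 with the block) and 0.806. Peritrophic matrix and mucin genes had a median of 0.54 over 8 genes (adjusted p 0.0282), with Mur29B at 1.55 (SE 0.34) the 1 member passing adjusted over the list alone and none over all probe sets. The call was lost without unmodified replicate 1. Antioxidant enzymes had a median of 0.19 over 10 genes (adjusted p 0.0477) with no member passing, a call lost under most alternatives, quantile normalization among them. Without 1 array the medians ranged from 0.12 to 0.45 for enteroendocrine peptides, 0.23 to 0.56 for progenitor markers and 0.27 to 0.67 for peritrophic matrix genes.

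**Figure D3:**
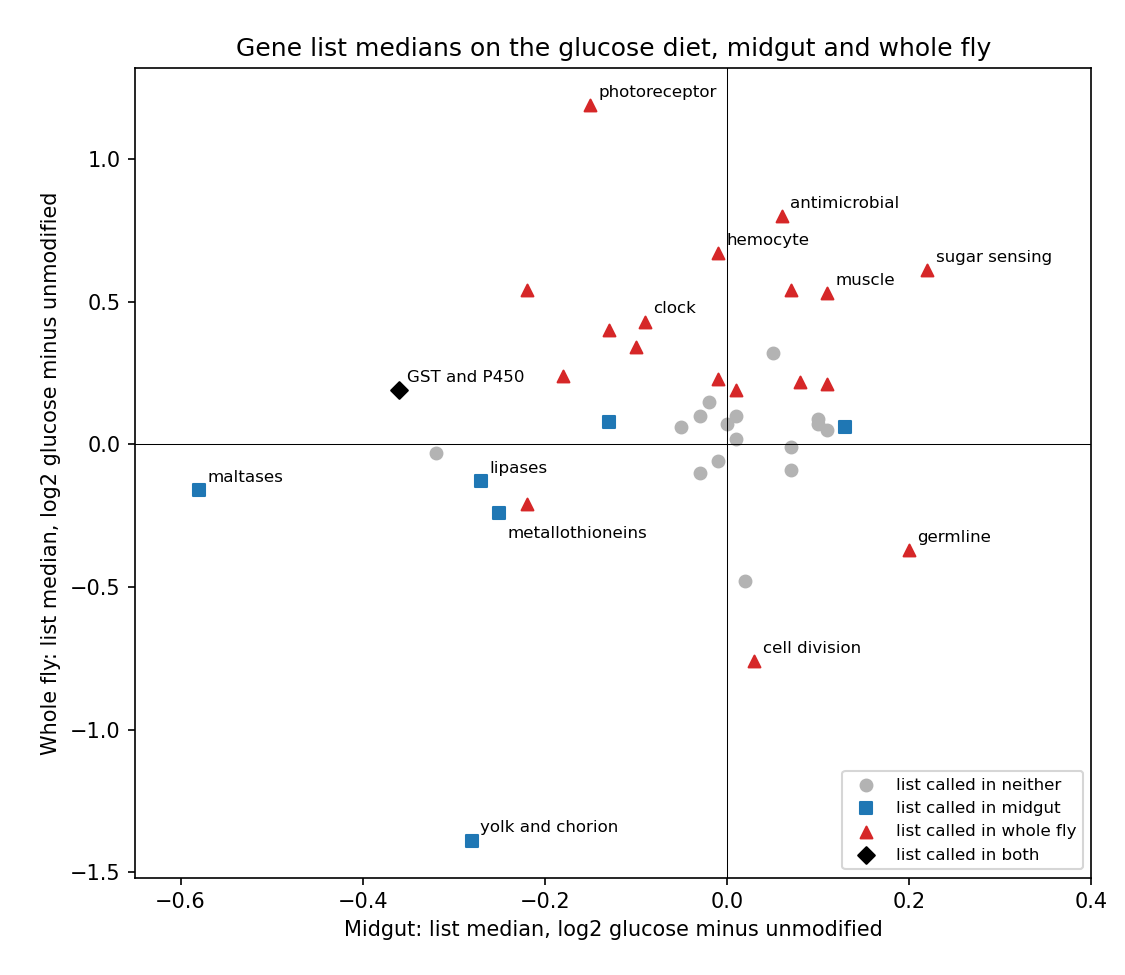
Median log2 difference, glucose minus unmodified, of each of the 41 gene lists in midgut (horizontal axis) and whole flies (vertical axis), with symbols for lists called by camera in neither tissue, 1 tissue or both. Photoreceptor genes stand at -0.15 in midgut and 1.19 in whole flies, and the maltase list at -0.58 and -0.16.

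The third comparison tested whether the effect of the diet differed between midgut and whole fly. The difference, midgut effect minus whole fly effect, passed for 8 probe sets, 7 positive and 1 negative, all with a limma adjusted p that rounds to 0.05, against 2833 at an unadjusted p under 0.05. The 5 named positive genes were cno at 1.52 (SE 0.21), the zinc finger gene jing at 1.25 (SE 0.19), CG2186 at 1.21 (SE 0.16), the centriole gene ana3 at 1.13 (SE 0.15) and the meiotic recombination gene rec at 1.06 (SE 0.16). The negative one was flap at -1.02 (SE 0.15). For cno the whole fly means were 7.38 ± 0.12 unmodified and 6.01 ± 0.25 on glucose (SD, n = 3), and the midgut means 3.50 ± 0.19 and 3.66 ± 0.18. The midgut means of jing, ana3, rec and flap lay between 2.05 and 3.20, below the array medians, and those of cno lay close to these medians. A fall such as that of cno, jing, ana3 and rec in whole flies could hardly show there. Their differences therefore mainly restate the values of the whole flies. A rise, as flap had in whole flies, could show from such a level, since CG13616 went from 2.95 to 4.33 in midgut. The midgut means of flap were 3.02 unmodified and 2.82 on glucose. Those of CG2186, which was lower on glucose in whole flies, were 5.19 and 5.23, above the array medians. A fall of CG2186 could have shown there, and none did. With the replicate block, whose numbers pair the midgut but not the whole fly samples, 749 probe sets were called, the 8 among them. None was called without the dimmest 40% of probe sets or with an intensity trend and robust prior, and after quantile normalization 21 were called, 61.9% of them positive against 87.5% as deposited. Without glucose replicate 2 of the whole flies the count was 361, and over the 12 fits without 1 array it ranged from 0 to 361.

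For gene lists, 15 of 41 differed between the tissues, 1 positive and 14 negative, and none did with an estimated correlation, where adjusted p-values lay between 0.159 and 0.592. With the replicate block 18 lists differed, the added ones being germline (blocked adjusted p 0.00304), peritrophic matrix and mucins (0.0193) and sugar sensing (0.0274). Detoxification genes had a median difference of -0.52 over 24 genes (adjusted p 3.13e-07; adjusted p = 0.159 with an estimated correlation), with 8 lower adjusted over the list alone and none over all probe sets. Photoreceptor genes had a median of -1.32 over 5 genes (adjusted p 3.17e-07; adjusted p = 0.305 with an estimated correlation), all 5 lower adjusted over the list alone and none over all probe sets. Their midgut means were 2.19 to 3.53, near or below the array medians, so this is the whole fly rise with its sign turned. Cell division genes, with midgut means of 2.94 to 6.21, had a median of 0.84 over 14 genes (adjusted p 0.00197; adjusted p = 0.525 with an estimated correlation) with no member passing, and 0.52 to 1.08 without 1 array.

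Diet calls shared by the tissues were counted next. The 1 midgut call, CG1648, was also called higher in whole flies, at 1.65 (SE 0.22), where 0.01 shared probe sets were expected (Fisher's exact test, one-sided, p = 0.0132), and no lower call was shared. With the replicate block in midgut, 5 higher calls were shared against 0.13 expected (Fisher's exact test, p = 9.05e-08) and 3 lower against 0.25 expected (p = 0.0018). At an unadjusted p under 0.05, 163 higher probe sets were shared against 61.4 expected (Fisher's exact test, p = 1.61e-32) and 55 lower against 61.3 expected (p = 0.825), while 128 went in opposite directions against 126 expected. Probe sets are not independent replicates, so these p-values overstate the evidence. Whole flies also include the midgut, so a shared call can be the same midgut change seen in both kinds of sample. The overlap therefore does not show a response in other tissues. Across all probe sets the diet effects of the 2 tissues had a Pearson correlation of 0.058 and a Spearman correlation of -0.002.

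The fourth comparison set midgut against whole fly on the unmodified diet. Whether the arrays of the 2 tissues were scaled together is not stated. The median difference over all probe sets was -0.139 as deposited and 0.475 with each array centred on its median, and the values below are as deposited. Of 10411 probe sets called, 2797 were higher in midgut and 7614 lower, or 26.9% higher, against 69.2% of 16043 after median centring and 54.2% of 10670 after quantile normalization. The vitamin transporter gene Smvt was higher in midgut by 6.19 (SE 0.49), from 4.76 ± 0.62 in whole fly to 10.9 ± 0.44 (SD, n = 3, limma adjusted p 1.84e-07). CG10553, CG10560, salt, the mannosidase gene LManIII, CG8834, CG6125, CG6602, CG31446 and CG5697 were higher by 4.24 to 4.92. Lower in midgut were the arrestin gene Arr2 at -8.49 (SE 0.18), the vitelline membrane genes Vm34Ca, Vm32E and Vm26Aa at -8.36, -7.89 and -7.56, Cp15 at -7.55, and the oogenesis genes orb and Marf1 at -7.94 and -7.60. CG34324, CG14645 and Scp1 were lower by -8.54, -7.82 and -7.55.

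Of the lists, 18 of 41 were called, 13 higher and 5 lower in midgut, and 1 of the higher ones, oxidative phosphorylation at 0.13, stood at -0.05 after quantile normalization. Secreted digestive proteases had a median of 2.45 and all 23 measured genes passed higher, over all probe sets and adjusted over the list alone (list adjusted p 2.85e-13). Enterocyte and copper cell markers had a median of 2.95 with 6 of 6 passing in both ways (list adjusted p 1.90e-05), and midgut progenitor markers 0.92 with 7 of 7 (list adjusted p 8.20e-05). Malpighian tubule markers were also higher, at a median of 3.15 over 7 genes with 6 passing in both ways (list adjusted p 3.58e-05). Germline genes had a median of -4.97 with all 13 lower, and cell division genes -4.79 with all 14 lower, in both ways of adjusting (list adjusted p 0.00137 and 1.39e-04). With an estimated correlation none of these lists was called, with adjusted p-values over the 18 lists between 0.138 and 0.442.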

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

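The tests of ovary share, enterocyte share, Malpighian tubule share, time of day and control transcripts in midgut were chosen after the results were seen; those on matched random lists, on control transcripts in whole flies, on left-out arrays and on other splits were set before their own results were seen.

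The genes whose diet effect differed between midgut and whole fly by the interaction test were cno (1.52), jing (1.25), CG2186 (1.21), ana3 (1.13), rec (1.06) and flap (-1.02). In midgut the means of jing, ana3, rec and flap lay between 2.05 and 3.20 and those of cno were 3.50 and 3.66. Those of the photoreceptor list lay between 2.19 and 3.53, against array medians of 3.433 to 3.469. At that level a fall could hardly show, while a rise could, as CG13616 went from 2.95 to 4.33. The midgut means of CG2186 lay higher, at 5.19 unmodified and 5.23 on glucose, where a fall could have shown and none did. These differences rest mainly on the whole fly change, and no midgut diet effect was called for these genes. Gene lists that differed in the same way, by median difference, were photoreceptor markers (-1.32), antimicrobial peptides (-0.87), hemocyte markers (-0.86), lysozymes (-0.85), detoxification genes (-0.52), muscle markers (-0.47), amylases and maltases (-0.44), peptidoglycan recognition and Imd pathway (-0.42), enteroendocrine peptides (-0.41), circadian clock (-0.33), midgut progenitors (-0.28), TCA cycle (-0.23), secreted serine proteases (-0.16), oxidative phosphorylation (-0.14) and cell division (0.84). All 15 list calls were lost with an estimated correlation, with adjusted p-values from 0.159 to 0.592. Of 100 groupings of the arrays within each tissue, 4 called at least the 8 probe sets of the real one, and the highest other called 131. That grouping keeps both diet splits and turns the sign in 1 tissue, so it adds the diet effects where the real one subtracts them. Of the 9 that kept the whole fly diet split and regrouped the midgut arrays, 2 called 62 and 31 and the other 7 called 0 to 2.

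In whole flies cell division and germline genes were lower on glucose while photoreceptor, muscle and hemocyte genes were higher. These were calls of camera, and with fry only the photoreceptor list was called (adjusted p 0.0396). The fry adjusted p was 0.0596 for cell division, 0.0519 for germline, 0.0911 for muscle and 0.066 for hemocyte genes. A smaller share of ovary RNA would raise all other tissues alike. The photoreceptor mean moved apart from the mean of neuron and Malpighian tubule markers by 1.14 (SE 0.19). That argues against a smaller ovary share as the whole cause for the photoreceptor genes only, the list with the largest median rise, chosen once the medians were known. The muscle (0.57, SE 0.19) and hemocyte means (0.78, SE 0.30) were not set against that reference, so for them a smaller ovary share stays open. It stays open for the genes that were lower as well. The neuron and Malpighian tubule mean differed by 0.03 (SE 0.15), and the ovary's share of the RNA is unknown. A smaller share therefore cannot be told apart from a change within the ovary. Against intensity-dependent scaling, all 5 list medians lay outside the central 95% of 10000 random lists matched on mean expression, and against RNA integrity, the list medians kept at least 0.84 of their size and their calls with the control transcript difference as a covariate. Changes in photoreceptor, muscle or blood cell transcripts, or in the body parts sampled, stay open and untested.

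In midgut the maltase, lipase, metallothionein and detoxification lists were lower on glucose; fewer enterocytes in the dissected tissue would lower enterocyte markers alike, but the mean of the 4 lists fell relative to the enterocyte list by 0.53 (SE 0.09), a difference between diets of -0.53. Malpighian tubule markers, higher in midgut than in whole fly by 3.15, stood at a mean of -0.28 (SE 0.17, or 0.07 as pairs) on glucose, and the 4 lists differed from them by -0.22 (SE 0.22, or 0.11 with same-numbered samples as pairs, which gave -0.41, -0.21 and -0.04), so less tubule tissue in the samples cannot be told apart with 3 pairs that range this widely. In 6 of 6 fits without 1 array the 4 lists kept their camera call, which argues against a single array as the whole cause, though the medians moved, from -0.14 to -0.68 for lipases and from -0.32 to -0.81 for maltases, and 4 of 4 list medians lay outside the central 95% of matched random lists, which argues against scaling by intensity. Against RNA integrity, the medians kept at least 0.90 of their size and their calls with the control transcript difference as a covariate. They were not all stable, since the lipase median went from -0.27 to -0.60 with it. On glucose the 3' to 5' difference of gapdh was higher in all 3 same-numbered pairs, by 0.04 to 0.46. The dap spike was higher too, by 0.46 to 0.47, for which no test was made. A response of midgut cells to the diet and a shift between midgut regions stay open and untested, and none of the lists was called with an estimated correlation.

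Circadian clock genes were higher in whole flies on glucose. Collection at a different time of day would be expected to move Clk and cry against per, tim and vri, whose transcripts peak in the opposite phase. The mean of Clk and cry was higher by 0.47 (SE 0.09) and that of per, tim and vri by 0.43 (SE 0.07), which argues against a plain shift of phase. A larger share of head or photoreceptor RNA, where clock genes are expressed, was not separated from a change in the clock genes.

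With 3 arrays against 3, 10 splits are too few for a share under 0.05. The real split called 1 probe set in midgut and the highest other 1, so that 2 of 10 reached the real count. Both are among the 4 splits that part all 3 same-numbered pairs, and those parting 1 pair called 0. In whole flies the real split called 584 and the highest other 1, and for midgut against whole fly 10411 and 0, so that in each 1 of 10, the real one, reached the count.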

How the results depend on the processing

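In midgut 1 probe set was called, against 10 with an intensity trend and robust prior, 24 with the replicate block, 6 in the fit over 12 arrays, 0 with the control transcript covariate, 46 at an unadjusted p with a 2-fold difference, and 0 to 0 over the 6 fits without 1 array. Of its 7 lists, 0 were called with an estimated correlation and 0 with fry, while 12 lists were called with the covariate and 6 to 11 without 1 array. The replicate block ended no midgut call of a gene or list, and those it added are given with the results.

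In whole flies 584 probe sets were called, against 1281 with array weights, 1711 with the replicate block, 1234 in the fit over 12 arrays, 1801 with the covariate, 119 with an adjusted p and a 2-fold difference, 247 at an unadjusted p with a 2-fold difference, and 0 to 1563 without 1 array. Of its 19 lists, 0 were called with an estimated correlation and 9 with fry, which called 10 lists in all. Without 1 array 17 to 20 lists were called. Same-numbered whole fly samples deviated with correlations of 0.20, 0.31 and -0.01, and unmodified replicate 3 correlated best with glucose replicate 1, at 0.22, so the numbers were not taken to pair them.

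For the difference of the diet effects 8 probe sets were called, against 0 without the 40% lowest means, 0 with the intensity trend and robust prior, 24 after median centring, 21 after quantile normalization, 47 with array weights, 749 with the replicate block, 315 at an unadjusted p with a 2-fold difference and 0 to 361 without 1 array. Of its 15 lists, 0 were called with an estimated correlation, 3 lists were called with fry and 11 to 19 without 1 array. For midgut against whole fly 10411 were called, against 16043 after median centring, 5980 with an adjusted p and 5985 with an unadjusted p and a 2-fold difference, and 9730 to 10450 without 1 array. Of its 18 lists, 0 were called with an estimated correlation, 37 lists were called with fry and 16 to 19 without 1 array, and oxidative phosphorylation turned to -0.05 after quantile normalization. Shared diet calls numbered 1 higher and 0 lower, against 163 and 55 at an unadjusted p.

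Of the named whole fly genes, 153 of 160 values under the alternatives other than left-out arrays kept their direction and call (adjusted p 0.0032 to 0.115), and 100 of 120 lost the call without 1 array, none turning. The named tissue genes kept both in 140 of 140 and 240 of 240. List calls kept both in 62 of 77 values in midgut (adjusted p 1.31e-10 to 0.859) and 168 of 209 in whole flies (adjusted p 1.08e-08 to 0.471), and without 1 array in 40 of 42 and 101 of 114. Without 1 array the medians of 4 of 7 midgut lists moved by over 1.5 times: maltases (-0.81 to -0.32), lipases (-0.68 to -0.14), serine proteases (-0.17 to -0.07) and yolk and chorion (-0.36 to -0.16). In whole flies 7 of 19 did: lysozymes (0.27 to 0.74), peritrophic matrix (0.27 to 0.67), progenitors (0.23 to 0.56), Imd pathway (0.22 to 0.52), enteroendocrine peptides (0.12 to 0.45), lipogenesis (0.08 to 0.35) and TCA cycle (0.12 to 0.30). For the difference of the diet effects 10 of 15 did: antimicrobial peptides (-1.31 to -0.59), lysozymes (-1.17 to -0.55), hemocyte (-1.14 to -0.53) and muscle markers (-0.74 to -0.36), enteroendocrine peptides (-0.58 to -0.21), maltases (-0.55 to -0.16), serine proteases (-0.34 to 0), TCA cycle (-0.27 to -0.12), oxidative phosphorylation (-0.20 to -0.07) and cell division (0.52 to 1.08). Midgut against whole fly had 0 of 18. Fits without 1 array have fewer samples; for the other moves the cause was not tested. Probe sets near background limit what can be seen in midgut, where array medians were 3.433 to 3.469.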

Other observations

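The families in the next paragraph were chosen after the data were seen, by the prefix of the gene symbol, and tested with camera over 19 families in each tissue.

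In midgut, genes of the mitochondrial ribosome were higher on glucose, alongside the cytosolic ribosomal protein genes. The large subunit family had a median of 0.24 over 44 genes (adjusted p 1.16e-08) and the small subunit family 0.27 over 25 genes (adjusted p 1.19e-04). Both calls were lost with an estimated correlation (adjusted p = 0.593 for both), and no member passed over all probe sets; the leading large subunit gene, mRpL18, stood at 0.29 (SE 0.10). Midgut glucose replicate 1 stood apart on the first principal component, at -35.4 against -5.2 to 19.2 in the other midgut samples, and carried oogenesis transcripts, with Marf1 at 5.62 against 2.44 and 2.35 in the other glucose samples, while unmodified replicate 1 had Marf1 at 4.35 against 2.21 and 2.42. Without glucose replicate 1 the medians were 0.13 and 0.13, with adjusted p-values of 0.00676 and 0.178. Without midgut unmodified replicate 3 the small subunit family had a median of 0.14 and an adjusted p of 0.0531. Without midgut glucose replicate 3 the medians rose to 0.41 for the large and 0.40 for the small subunit family. In whole flies the small subunit family had a median of 0.10 (adjusted p 0.0488) and the large subunit family 0.07 (adjusted p 0.136). There 8 of the 19 families were called, all higher by the test of the family. Genes with the Cyp prefix, cytochrome P450s but for the cyclophilin genes Cyp1 and Cyp40 (median 0.23 over 83 genes, adjusted p 9.32e-05) and Nep metalloprotease genes (median 0.42 over 26 genes, adjusted p 5.51e-05) were among them, with 4 and 1 members passing over all probe sets, among them Cyp4p1 at 0.88 (SE 0.17) and Nepl11 at 0.95 (SE 0.19). Cuticle protein genes with the Cpr prefix had a median of 0.08 over 66 genes (adjusted p 0.00207), with Cpr66D at 1.38 (SE 0.23) and Cpr49Ae at 0.82 (SE 0.11) passing. The others were Spn (median 0.28, adjusted p 0.00557), Tsp (0.28, adjusted p 0.0202), Obp (0.10, adjusted p 0.0202) and Ugt (0.14, adjusted p 0.0319). The 1 member of these 4 to pass over all probe sets, Tsp97E, was lower, at -0.63 (SE 0.11), against the direction of its family. With an estimated correlation none of the 8 was called, with adjusted p = 0.501 for Cyp, 0.489 for Nep and Obp, 0.401 for Cpr, 0.787 for Spn and Tsp, and 0.788 for Ugt and the small subunit family.

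Of the 584 probe sets called in whole flies, 60 had an unadjusted p under 0.05 in midgut, 45 in the same direction and 15 in the opposite one; of all 584, 329 had the same sign in midgut. Whole flies include the midgut, so a difference in the same direction can be the same midgut change. The genes named here were chosen after their values were seen. In the same direction, CG8093 stood at -2.32 in midgut and -2.04 in whole flies, CG6283 at -1.26 and -1.27, Mal-A4 at -1.22 and -1.11, AkhR at 0.56 and 1.58, and the perlecan gene trol at 0.73 and 0.86 for 1 of its probe sets. In the opposite direction, Akh stood at -0.32 and 0.75, Cyp6a2 at -0.42 and 0.76, and GstD2 at -1.07 and 1.35. Their unadjusted limma p-values in midgut were 0.0188, 0.0419 and 0.0486. At an unadjusted p under 0.05 in both tissues, 128 probe sets went in opposite directions against 126 expected. Opposite effects were thus no more frequent than expected over all probe sets, a count that cannot decide for single genes. For Akh, Cyp6a2 and GstD2 opposite regulation stays open, since none of them passed over all probe sets in midgut. The detoxification list, which holds Cyp6a2 and GstD2, was called by camera in both tissues, in opposite directions. Its median was -0.36 in midgut (adjusted p 6.63e-09) and 0.19 in whole flies (adjusted p 0.0171). Neither call held with an estimated correlation (adjusted p = 0.199 and 0.322).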
